A study of Gallus gallus with 12 samples.

How the data were processed

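Gene expression was measured in hearts of chicken embryos on 12 Affymetrix chicken genome arrays. The labels give 3 breeds, Tibetan, Shouguang and Dwarf Recessive White, each incubated in hypoxia and in normoxia, with 2 arrays in each of the 6 groups. Per the labels, total RNA was extracted with TRIzol and biotinylated cRNA was made by the standard Affymetrix protocol. The oxygen level, the day of incubation, the sex of the embryos and the number of hearts behind an array are not given in the sources used here.

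The deposited values are signal intensity per probe set on a linear scale, made by the authors with the GCOS software, per the submitters' processing notes; the software's version is not given in the sources used here. Tested on the values, the mean signal of each array, with the highest and the lowest 2% of values left out, was 500.1, so the arrays had been scaled to a common mean. The deposited table holds 38535 probe sets. The 96 control probe sets were left out, the signals were put on the log2 scale and no further normalization between arrays was applied. Probe sets with a mean log2 signal under the 40th percentile (a signal of 79.5) were left out, which kept 23063 probe sets for testing.

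Probe sets were named with a table of gene symbols. In it, 27178 probe sets had 1 symbol, 177 had several and 11180 had none; only probe sets with 1 symbol were named. A reference gene table of the GRCg7b assembly was used to update symbols and to place genes on the Z or W chromosome, and its coordinates were not used. Of the 10276 genes tested under 1 symbol, 5420 had 1 tested probe set and 4856 had several.

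Each probe set was fitted in R 4.3.3 with limma 3.58.1, with a mean for each of the 6 groups and variances moderated with an intensity trend (6 residual and 6.16 prior degrees of freedom). The contrasts were hypoxia minus normoxia within each breed, its mean over the 3 breeds, the 3 differences of that effect between breeds, the 3 differences between breeds averaged over both conditions, and Tibetan minus the mean of the other breeds within normoxia and within hypoxia. Tests were two-sided, p-values were adjusted by the Benjamini-Hochberg method over all tested probe sets within a contrast, and the threshold was an adjusted p of 0.05. Effects are log2 changes ± the limma standard error (SE), from 2 arrays per group unless stated otherwise. A p-value here measures a difference only against the spread between these arrays, which may be technical as well as biological. With arrays, it is their number that limits the precision: the median SE was 0.26 for a within-breed effect, 0.15 for the mean hypoxia effect, 0.37 for a difference of effects and 0.19 for a breed difference.

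In total 28 gene lists (pathways, cell types of the heart, neighbouring tissues and W-linked genes) were used, with 1 probe set per gene, the one with the highest mean signal. They hold 953 genes, of which 701 were measured. In 24 of the 962 list places (23 measured) the gene was reached through an older name, which brought in relatives such as ALAS1 in the red blood cell list and PGK2, PKLR and SLC2A14 in the glycolysis list. Lists with at least 5 measured genes, 27 of them, were tested with limma's camera at a preset correlation between genes of 0.01, with an estimated correlation as an alternative, adjusted over the lists of a contrast. A list call at the preset correlation assumes that its genes vary nearly independently between arrays. In every list that passed, the median, the mean and the test had the same sign.

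The named genes follow a rule: among passing probe sets with 1 symbol, the 8 highest and the 8 lowest changes with complete separation of the arrays compared; where fewer than 5 passed, the 5 smallest p-values; up to 4 passing members of each list; and a fixed set of hypoxia, heart, globin and W-linked genes. Where a gene has several probe sets, the one with the smallest p is reported. Where most arrays on one side of a comparison lie under the dim limit (a signal of 79.5), the change is also given with signals under the limit raised to it, a step added after the data had been seen. The contrasts, the tests, the lists, this rule and all alternatives but a pair were chosen before the data were examined.

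The alternatives were no filter and a stricter filter (60th percentile) on dim probe sets, quantile normalization, median centring, an offset of 26.6 before the log, no intensity trend, array weights, the replicate number as a block, fits with only the arrays compared, 1 probe set per gene, other thresholds (an adjusted p of 0.1; a change of at least 2-fold), and leaving out each array in turn. The pair added after the data had been seen were the mean W-linked level of an array as a covariate and leaving out genes on Z and W. The procedure was tested on simulated data with 200 changed probe sets. The noise was drawn independently for each probe set and array, without the differences by replicate number and W-linked level seen on the real arrays. The rates hold for such data and may not carry over to these arrays. For the mean hypoxia contrast it recovered 73% of 2-fold and 94% of 4-fold changes with 7 unchanged probe sets among 174 calls. For a within-breed effect it recovered 42% and 84% (12 unchanged among 138 calls), for a difference of effects 16% and 59% (8 among 83), and for a breed difference 63% and 92% (3 among 158). Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.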

Results

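Transcript levels in the embryonic heart were measured on 12 arrays, 2 for each combination of 3 chicken breeds and 2 incubation conditions. The Tibetan chicken is a highland breed, Shouguang and Dwarf Recessive White are breeds of lower altitude, and the title of the series asks how hypoxia affects the hearts of their embryos. The median signal of an array lay between 134 and 155. Pearson correlations between arrays, across probe sets on the log2 scale, were 0.949 to 0.960 within a group, 0.946 to 0.962 between the conditions of a breed and 0.937 to 0.956 between breeds. Genes of the W chromosome, which only females carry, differed between arrays: HINTW had a log2 signal of 7.74 on Dwarf Recessive White normoxia replicate 1 and of 12.10 to 14.42 on the other arrays. The mean log2 signal of the W-linked genes ranged from 6.01 to 9.60. Over the 12 arrays, the mean of 14 W-linked genes and that of 476 Z-linked genes relative to 9665 autosomal genes had a Pearson r of -0.782 (two-sided permutation p = 0.0003) and a Spearman rho of -0.860 (two-sided permutation p = 0.0006). The Pearson r was -0.890 without the 2 arrays farthest from the median W-linked level, and -0.966 and -0.947 within the arrays numbered replicate 1 and replicate 2.

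**Figure D1:**
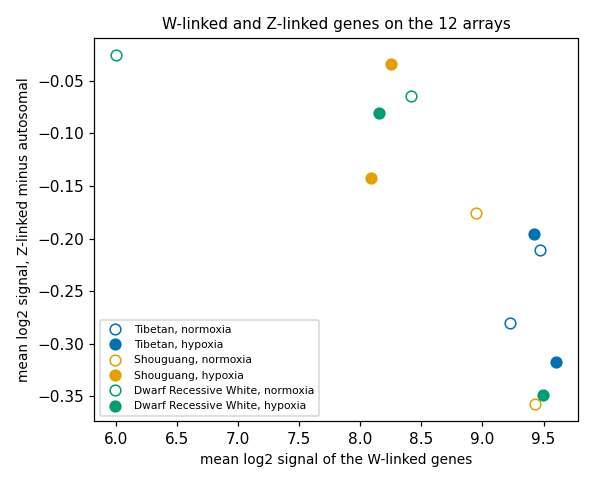
Mean log2 signal of the Z-linked minus the autosomal genes against the mean log2 signal of the W-linked genes on the 12 arrays, coloured by breed, with open circles for normoxia and filled circles for hypoxia. Dwarf Recessive White normoxia replicate 1 lies farthest left, at 6.01, and arrays with less W-linked signal have more Z-linked signal.

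Averaged over the 3 breeds, hypoxia changed 13 probe sets. The comparison tests the mean of the within-breed effects, so a gene or list can pass without a change in every breed. CCN2, a matrix-associated growth factor of the connective tissue, rose by 0.99 ± 0.09 (SE, n = 6 arrays per condition, adjusted p = 0.00243), and MGP, an inhibitor of calcification, by 0.84 ± 0.08 (adjusted p = 0.00243). GLRX, which encodes a glutaredoxin, rose by 1.14 ± 0.14 and BLB1, a major histocompatibility complex class II beta chain, by 1.13 ± 0.13 (adjusted p = 0.0124 each). ALB (serum albumin) fell by 2.83 ± 0.41 and TTR (transthyretin) fell by 1.62 ± 0.24 (adjusted p = 0.0378 each). All 12 hypoxia and normoxia arrays were separated within each breed for these 6 genes.

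SDR42E2 also rose, by 1.21 ± 0.18, and ACCSL by 1.01 ± 0.15 (adjusted p = 0.0378 each). THBS4, a matrix thrombospondin, fell by 0.66 ± 0.09 (adjusted p = 0.0329) and FKBP1B, which binds the ryanodine receptor of the sarcoplasmic reticulum, fell by 0.49 ± 0.07 (adjusted p = 0.0378). These 10 genes account for all named probe sets among the 13 that passed (8 up, 5 down; 1927 at an unadjusted p under 0.05, with 1153 expected by chance). BLB1 has 4 tested probe sets, and only the one with the smallest p is given. A second one moved by 0.96 for SDR42E2 and by 0.42 for ACCSL. The other genes have 1 each. CCN2 and MGP passed in all 12 fits that left out an array, GLRX and BLB1 in 8, and the other 6 genes in 1 to 3 of them. GLRX lost its call without Dwarf Recessive White normoxia replicate 1, Shouguang normoxia replicate 1, Tibetan hypoxia replicate 1 or Tibetan normoxia replicate 2, with adjusted p-values from 0.00564 to 0.131 over all fits. BLB1 lost it without Dwarf Recessive White hypoxia or normoxia replicate 1, Shouguang normoxia replicate 1 or Tibetan normoxia replicate 2, with adjusted p-values from 0.00393 to 0.170. The count of probe sets was 2 without Shouguang normoxia replicate 1 or Tibetan normoxia replicate 2. It was 3 without Tibetan hypoxia replicate 1, Dwarf Recessive White hypoxia replicate 1 or Dwarf Recessive White normoxia replicate 1, and 6 without Shouguang normoxia replicate 2 or Tibetan hypoxia replicate 2. It was 0 without the intensity trend, 4 without the filter on dim probe sets and 7 with the W-linked level as a covariate, but 32 with 1 probe set per gene, 26 with the stricter filter, 24 with the offset and 20 with median centring. The covariate ended the calls of SDR42E2, ACCSL, ALB, THBS4 and FKBP1B. The count rose with the replicate number as a block, as given in the part on processing.

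**Figure D2:**
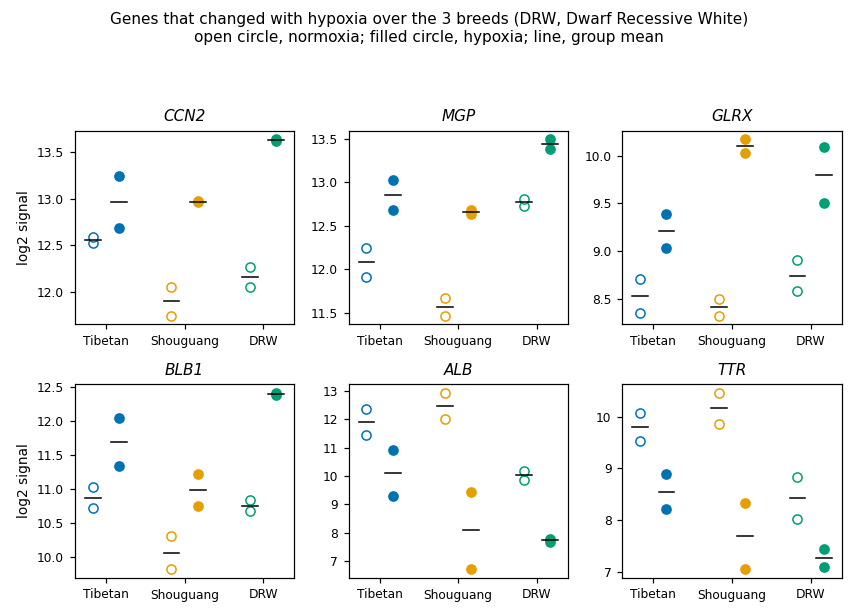
Log2 signal of 6 genes on the 12 arrays, by breed, with open circles for normoxia, filled circles for hypoxia and a line at the mean of each group of 2 arrays. In every breed both hypoxia arrays lie above both normoxia arrays for CCN2, MGP, GLRX and BLB1, and below them for ALB and TTR; ALB spans 6.72 to 12.94.

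The plasma protein genes made in liver and yolk sac, a list of a neighbouring tissue, fell as a group. Of 11 measured genes 9 lay below 0, with a median of -1.37 (camera adjusted p = 2.29e-06; adjusted p = 0.178 with an estimated correlation). Over all probe sets 2 fell, and adjusted over the list alone 7 fell and 1 rose. Besides ALB and TTR, AHSG (-4.05 ± 0.67, adjusted p = 0.0535) and the fibrinogen chains FGB (-1.37 ± 0.28) and FGG (-1.64 ± 0.40) fell over the list alone, while APOA1, an apolipoprotein, rose (0.71 ± 0.17). AHSG lay under the dim limit, the signal of 79.5 used as the filter, on 5 of 6 hypoxia arrays, and fell by 1.91 with signals under the limit raised to it. ALB differed between arrays of a group as well, with log2 signals of 6.72 and 9.45 in Shouguang hypoxia.

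Genes of early response to stimuli rose as a group, with a median of 0.15 and 14 of 16 above 0 (adjusted p = 2.29e-06; adjusted p = 0.0827 with an estimated correlation). Over all probe sets 0 passed in limma, and adjusted over the list alone 6 rose. They were the transcription factors JUN (0.45 ± 0.09), MYC (0.47 ± 0.10), EGR1 (0.73 ± 0.18) and ATF3 (1.01 ± 0.25), the matrix protein gene CYR61 (0.69 ± 0.19) and BTG2 (0.30 ± 0.08), which restrains proliferation. Genes of endoplasmic reticulum stress rose with a median of 0.10, 24 of 30 above 0 (adjusted p = 0.00296; adjusted p = 0.249 with an estimated correlation), with no member passing, adjusted over the list alone. HSPA5 stood at 0.26 and PDIA6 at 0.30.

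Oxidative phosphorylation genes fell together by a small amount: 53 of 58 lay below 0, with a median of -0.08 (adjusted p = 8.59e-09; adjusted p = 0.284 with an estimated correlation). No member passed, either over all probe sets or adjusted over the list alone; CYCS stood at -0.22 and NDUFA8 at -0.20. The tricarboxylic acid cycle (median -0.06, 14 of 17 below 0, adjusted p = 0.0126; adjusted p = 0.284 with an estimated correlation) and cholesterol synthesis (-0.19, 14 of 17, adjusted p = 0.023; adjusted p = 0.31 with an estimated correlation) also fell. So did antioxidant defence (-0.06, 24 of 34, adjusted p = 0.023; adjusted p = 0.178 with an estimated correlation). None of their members passed, adjusted over the list alone. Cell cycle genes fell with a median of -0.10, 51 of 62 below 0 (adjusted p = 2.29e-06; adjusted p = 0.284 with an estimated correlation). Over the list alone 1 member, the mitotic kinase AURKB (-0.35 ± 0.08), fell. The call of the tricarboxylic acid cycle ended without Shouguang or Tibetan hypoxia replicate 1 (adjusted p up to 0.133), and that of antioxidant defence without hypoxia replicate 1 of any breed (up to 0.0684). Cholesterol synthesis lost its call with a stricter filter and without Dwarf Recessive White hypoxia or normoxia replicate 1, Shouguang hypoxia replicate 2, Shouguang normoxia replicate 1 or Tibetan normoxia replicate 1 (up to 0.155).

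Among the cell types of the heart, genes of cardiomyocyte contraction and calcium handling fell slightly, with a median of -0.06 and 34 of 45 below 0 (adjusted p = 0.00822; adjusted p = 0.294 with an estimated correlation). The call ended with quantile normalization and without Shouguang hypoxia replicate 1 (adjusted p = 0.136). By the adjustment over the list alone, MB (myoglobin, -0.24 ± 0.05) and CKMT2 (mitochondrial creatine kinase, -0.47 ± 0.13) fell, and GJA1 (a gap junction protein, 0.47 ± 0.10) and ANKRD1 (a stretch-responsive gene, 0.80 ± 0.21) rose. Smooth muscle and pericyte genes fell (median -0.19, 8 of 10 below 0, adjusted p = 0.00959; adjusted p = 0.178 with an estimated correlation), with MYLK (-0.31 ± 0.08) and MYL9 (-0.22 ± 0.06) passing, adjusted over the list alone. Extracellular matrix and fibroblast genes rose (median 0.05, 28 of 44 above 0, adjusted p = 0.0122; adjusted p = 0.292 with an estimated correlation), with CCN2 alone passing; the call ended without Shouguang hypoxia replicate 1, Shouguang normoxia replicate 1 or Tibetan normoxia replicate 1 (adjusted p up to 0.159). Red blood cell genes rose (median 0.14, 17 of 20 above 0, adjusted p = 0.00271; adjusted p = 0.284 with an estimated correlation). The red blood cell genes SLC25A37 (an iron importer of the mitochondrion, 0.38 ± 0.09), TSPO2 (0.51 ± 0.14) and EPB42 (0.40 ± 0.12) rose, adjusted over the list alone, and ALAS1 (-0.37 ± 0.07), the housekeeping form of the first enzyme of haem synthesis, fell. Cytosolic ribosomal protein genes rose (median 0.04, 48 of 64 above 0, adjusted p = 0.00132; adjusted p = 0.479 with an estimated correlation), with RPL31 (0.63 ± 0.10) passing, adjusted over the list alone. Without Shouguang hypoxia replicate 1 the red blood cell call ended (adjusted p = 0.0501), and without Shouguang hypoxia replicate 2 the ribosomal one (adjusted p = 0.0658). The 4 measured W-linked genes of the list had a median of 0.35, and -1.72 in Shouguang against 2.72 in Dwarf Recessive White.

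The lists closest to the oxygen-sensing pathway did not pass. Glycolysis and glucose transport had a median of 0.03, 17 of 26 above 0 (adjusted p = 0.0982). Over the list alone LDHA, a lactate dehydrogenase subunit (0.41 ± 0.07, adjusted p = 0.0539 over all probe sets), and the lactate transporter SLC16A3 (0.71 ± 0.15) rose. Targets of the hypoxia-inducible factor (HIF) outside glycolysis had a median of 0.04, 22 of 33 above 0 (adjusted p = 0.437), with FAM162A (-0.27 ± 0.06) lower over the list alone. HIF pathway regulators had a median of -0.06, 8 of 12 below 0 (adjusted p = 0.422), with ARNT2 (-0.35 ± 0.10) lower over the list alone. The genes always named, each read by its probe set with the highest mean signal, did not pass. The angiogenic factor VEGFA stood at -0.11 ± 0.12, ADM at 0.04 ± 0.11, EGLN3 at 0.15 ± 0.19, PDK1 at -0.09 ± 0.06 and the glucose transporter SLC2A1 at 0.11 ± 0.09. BNIP3 stood at 0.21 ± 0.07, NDRG1 at 0.12 ± 0.08, and the HIF subunits HIF1A and EPAS1 at -0.11 ± 0.09 and -0.07 ± 0.11. The atrial natriuretic peptide gene NPPA (0.01 ± 0.04), MYH7B (-0.12 ± 0.07), the globin genes HBA1 (-0.08 ± 0.04) and HBE (0.42 ± 0.18) and HINTW (0.52 ± 0.65) complete the set, with adjusted p-values from 0.370 (BNIP3) to 0.985 (NPPA).

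The remaining lists did not pass either. The medians were -0.03 for fatty acid oxidation (13 of 27 above 0, adjusted p = 0.844), and -0.06 for cardiac transcription factors (12 of 16 below 0, adjusted p = 0.437). They were 0.03 for endothelium and angiogenesis (20 of 36 above 0, adjusted p = 0.231) and -0.03 for epicardium (4 of 8 above 0, adjusted p = 0.879). They were 0.06 for leukocytes and macrophages (11 of 21 above 0, adjusted p = 0.111), and 0.16 for platelets (6 of 7 above 0, adjusted p = 0.104). Neural tissue had a median of 0.14 (5 of 9 above 0, adjusted p = 0.437) and skeletal muscle of -0.08 (6 of 10 below 0, adjusted p = 0.422). Heat shock proteins had a median of 0.02 (20 of 36 above 0, adjusted p = 0.285), and apoptosis genes -0.01 (15 of 28 below 0, adjusted p = 0.851). Lung and gut epithelium had a median of -0.06 while its test pointed up (adjusted p = 0.851); for fatty acid oxidation and apoptosis the mean had the opposite sign to the median. Single members passed when adjusted over the list alone: SOX7 (0.35 ± 0.08) and CXCR4 (0.46 ± 0.11) of the endothelium and KRT7 (0.39 ± 0.10) of the epithelium rose. TNNC2 (-1.48 ± 0.28), MYL1 (-0.49 ± 0.14) and ACTA1 (-0.13 ± 0.04) of skeletal muscle fell, adjusted over the list alone.

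**Figure D3:**
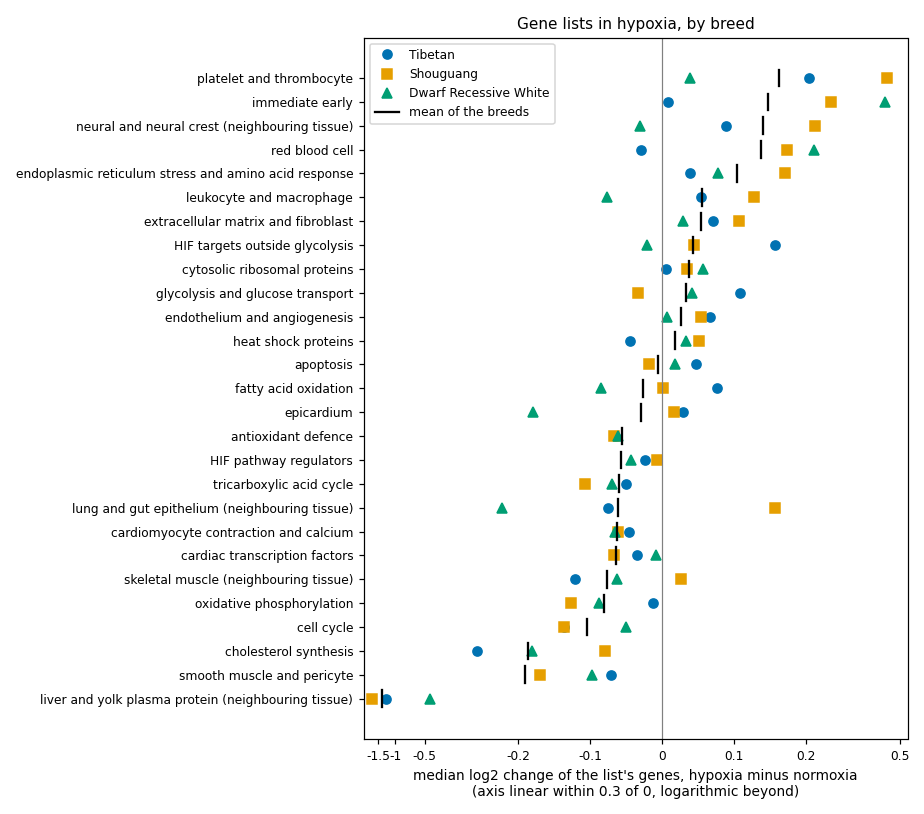
Median log2 change with hypoxia of the 27 tested gene lists in Tibetan (circles), Shouguang (squares) and Dwarf Recessive White (triangles) hearts, from 2 arrays per group, with a line at the mean effect of the breeds; the axis is linear within 0.3 of 0 and logarithmic beyond. The liver and yolk plasma protein genes lie lowest in every breed, at -1.24, -1.74 and -0.44, and oxidative phosphorylation lies below 0 in every breed.

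Within the Tibetan breed, glycolytic and other HIF target genes were higher in hypoxia as groups. Glycolysis and glucose transport rose with a median of 0.11, 20 of 26 above 0 (adjusted p = 4.91e-05; adjusted p = 0.433 with an estimated correlation). LDHA (0.68 ± 0.12, n = 2 arrays per condition) and SLC16A3 (1.08 ± 0.26) rose, adjusted over the list alone. HIF targets outside glycolysis rose with a median of 0.16, 23 of 33 above 0 (adjusted p = 0.0447; adjusted p = 0.433 with an estimated correlation), with no member passing, adjusted over the list alone. Cell cycle genes fell (median -0.14, 46 of 62 below 0, adjusted p = 0.000156; adjusted p = 0.547 with an estimated correlation), and NUF2, a kinetochore gene, fell over the list alone (-1.12 ± 0.20). The plasma protein genes of liver and yolk fell (median -1.24, 9 of 11 below 0, adjusted p = 0.000651; adjusted p = 0.433 with an estimated correlation). In limma 0 probe sets passed (1027 at an unadjusted p under 0.05). The smallest p-values belonged to GJD2, a neuronal gap junction gene (-2.24 ± 0.36, adjusted p = 0.405; -1.68 against the dim limit, under which both hypoxia arrays lay), LDHA, NES (-0.84 ± 0.15), NUF2 and MGP (0.77 ± 0.14, adjusted p = 0.469). Without Tibetan hypoxia replicate 2 the count was 9, without Tibetan normoxia replicate 1 it was 3 and without Tibetan hypoxia replicate 1 it was 2. Without Tibetan normoxia replicate 2 the glycolysis (adjusted p = 0.0685) and cell cycle lists (adjusted p = 0.069) no longer passed. The plasma protein call ended without Tibetan hypoxia replicate 2 or Tibetan normoxia replicate 1 (up to 0.279) and with the stricter filter. The HIF target list passed only without Tibetan normoxia replicate 1, Dwarf Recessive White normoxia replicate 2 or either Dwarf Recessive White hypoxia array, and it was lost without each of the other 8 (up to 0.415), with no filter, with a stricter one, with median centring and without the genes on Z and W.

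Within the Shouguang breed, the matrix gene MGP stood at 1.09 ± 0.14 (adjusted p = 0.111) and GLRX at 1.69 ± 0.24 (adjusted p = 0.122). BMP10, a growth factor of the embryonic heart wall, stood at 3.08 ± 0.46 and CCN2 at 1.07 ± 0.16 (adjusted p = 0.131 each). ALB stood at -4.39 ± 0.71 (adjusted p = 0.217), and none of the 5 passed over all probe sets. As groups, oxidative phosphorylation genes fell (median -0.13, 54 of 58 below 0, adjusted p = 1.16e-09; adjusted p = 0.279 with an estimated correlation). The tricarboxylic acid cycle (-0.11, 15 of 17, adjusted p = 0.0118; adjusted p = 0.279 with an estimated correlation) and the cell cycle (-0.14, 50 of 62, adjusted p = 7.51e-05; adjusted p = 0.374 with an estimated correlation) fell too. Plasma protein genes fell with a median of -1.74 (9 of 11 below 0, adjusted p = 7.37e-08; adjusted p = 0.155 with an estimated correlation). Of its members 6 fell, adjusted over the list alone, among them AHSG (-5.48 ± 1.16) and FGB (-2.24 ± 0.48). AHSG lay under the dim limit on both hypoxia arrays, so that its size is a bound only; it was -3.11 with signals under the limit raised to it. Smooth muscle genes fell (-0.17, 9 of 10, adjusted p = 0.0312; adjusted p = 0.279 with an estimated correlation), MYL9 (-0.35 ± 0.10) over the list alone. Immediate early genes rose (0.23, 15 of 16 above 0, adjusted p = 0.000851; adjusted p = 0.155 with an estimated correlation). So did endoplasmic reticulum stress (0.17, 20 of 30, adjusted p = 0.0118; adjusted p = 0.279 with an estimated correlation), with the chaperone HSPA5 (0.53 ± 0.13) passing over the list alone. Matrix and fibroblast genes (0.11, 29 of 44, adjusted p = 0.00151; adjusted p = 0.279 with an estimated correlation) and red blood cell genes (0.17, 16 of 20, adjusted p = 0.00347; adjusted p = 0.279 with an estimated correlation) rose too. Ribosomal protein genes rose by less (0.03, 46 of 64, adjusted p = 0.0149; adjusted p = 0.635 with an estimated correlation). The ribosomal call ended without Shouguang normoxia replicate 2, and without Shouguang hypoxia replicate 2, where the median was -0.0023 (adjusted p = 0.865). Leaving out Shouguang hypoxia replicate 1 or Shouguang normoxia replicate 1 ended the calls of the tricarboxylic acid cycle (adjusted p up to 0.548), the matrix (0.403), red blood cells (0.484) and endoplasmic reticulum stress (0.107). The smooth muscle call ended without Shouguang hypoxia replicate 2 or Shouguang normoxia replicate 1 (up to 0.375), and with no filter, median centring or the W-linked covariate (0.102). The W-linked covariate ended the red blood cell call and median centring that of the tricarboxylic acid cycle. In limma 0 probe sets passed (1273 at an unadjusted p under 0.05). The count was 3 without Shouguang hypoxia replicate 2, and 2 without Tibetan hypoxia replicate 1, without Tibetan hypoxia replicate 2 or with 1 probe set per gene.

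Within the Dwarf Recessive White breed, CCN2 rose by 1.48 ± 0.16 (n = 2 arrays per condition, adjusted p = 0.0192), the only probe set to pass (1461 at an unadjusted p under 0.05). Immediate early genes rose as a group, with a median of 0.35 and 13 of 16 above 0 (adjusted p = 1.18e-07; adjusted p = 0.0408 with an estimated correlation). Adjusted over the list alone 7 members rose, among them MYC (0.84 ± 0.17), JUN (0.75 ± 0.16), ATF3 (1.93 ± 0.44) and CYR61 (1.39 ± 0.32). Red blood cell genes rose (0.21, 17 of 20, adjusted p = 0.00834; adjusted p = 0.528 with an estimated correlation). Over the list alone the embryonic globin gene HBE (1.28 ± 0.32) and SLC25A37 (0.64 ± 0.16) rose and ALAS1 (-0.47 ± 0.13) fell. Cardiomyocyte genes fell (-0.07, 34 of 45, adjusted p = 0.00834; adjusted p = 0.528 with an estimated correlation). Over the list alone ANKRD1 (1.92 ± 0.37) rose while CKMT2 (-1.14 ± 0.22) and MB (-0.38 ± 0.08) fell. Oxidative phosphorylation (-0.09, 52 of 58, adjusted p = 3.12e-06; adjusted p = 0.528 with an estimated correlation) and cholesterol synthesis (-0.18, 14 of 17, adjusted p = 0.0376; adjusted p = 0.528 with an estimated correlation) fell. Smooth muscle genes fell as well (-0.10, 9 of 10, adjusted p = 0.0376; adjusted p = 0.388 with an estimated correlation). Ribosomal protein genes rose (0.06, 46 of 64, adjusted p = 0.00806; adjusted p = 0.72 with an estimated correlation). BLB1 (1.65 ± 0.23, adjusted p = 0.0995), THBS4 (-1.11 ± 0.16, adjusted p = 0.0995), APCDD1 (-3.42 ± 0.57, adjusted p = 0.226; -1.04 against the dim limit, under which both hypoxia arrays lay) and MFAP5 (-0.98 ± 0.16, adjusted p = 0.226) followed. HINTW stood at 3.32 ± 1.12, with log2 signals of 7.74 and 12.93 on the normoxia arrays. CCN2 lost its call without the intensity trend, with the W-linked level as a covariate and in 7 of the 12 fits that left out an array, with adjusted p-values from 0.00202 to 0.394 over all of these fits. The 7 arrays were both of Dwarf Recessive White hypoxia, both of Shouguang hypoxia, both of Tibetan normoxia and Dwarf Recessive White normoxia replicate 1. Leaving out an array of this breed also ended list calls: smooth muscle without any of its 4 arrays (adjusted p up to 0.148), cholesterol synthesis without either replicate 1 (0.511), and red blood cells without either replicate 2 (0.337). Cardiomyocyte genes lost theirs without hypoxia replicate 2 (0.0692), and ribosomal genes without hypoxia replicate 1 or normoxia replicate 2 (0.369). The cholesterol call also ended with no filter, a stricter filter, the W-linked covariate (0.647) and without the genes on Z and W. Without Dwarf Recessive White normoxia replicate 2 the count was 23, all higher, and without Dwarf Recessive White normoxia replicate 1 it was 0.

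Differences of the hypoxia effect between breeds test whether the hearts respond differently. In limma 0 probe sets passed for each of the 3 differences (665 at an unadjusted p under 0.05 for Tibetan minus Shouguang, 922 for Tibetan minus Dwarf Recessive White and 1051 for Shouguang minus Dwarf Recessive White, with 1153 expected). The smallest p-values belonged to AMD1 (1.52 ± 0.30), TRIM47 (1.19 ± 0.26), IGHMBP2 (1.39 ± 0.31), SLA (2.73 ± 0.61) and C1orf158 (2.08 ± 0.47) for Tibetan minus Shouguang. For Tibetan minus Dwarf Recessive White they were HSPB9, a small heat shock protein gene (-0.83 ± 0.14), TGM4 (-1.70 ± 0.30), MAP3K4 (-1.05 ± 0.20), ELMOD3 (-3.59 ± 0.71; -1.10 against the dim limit) and KIF1B (1.49 ± 0.30). TGM4 (-1.76 ± 0.30), APCDD1 (4.60 ± 0.80), BMP10 (3.56 ± 0.65), the W-linked LOC107049459 (-3.09 ± 0.58) and FAP (2.68 ± 0.54) came first for Shouguang minus Dwarf Recessive White; adjusted p-values were 0.998 to 1. By camera at the preset correlation, 12 combinations of a list and a pair of breeds passed, and 0 with an estimated correlation. For glycolysis Tibetan exceeded Shouguang by a median of 0.20 (25 of 26 above 0, adjusted p = 7.11e-06; adjusted p = 0.607 with an estimated correlation). For immediate early genes Tibetan lay below Dwarf Recessive White by a median of -0.36 (12 of 16 below 0, adjusted p = 0.000135; adjusted p = 0.141 with an estimated correlation). Both calls held without any array in turn. The count rose to 2 without Shouguang hypoxia replicate 2 for Tibetan minus Shouguang. It rose to 7 without Dwarf Recessive White normoxia replicate 2 for Tibetan minus Dwarf Recessive White, and to 15 without it for Shouguang minus Dwarf Recessive White. Single probe sets passed without Shouguang hypoxia replicate 1 or Tibetan normoxia replicate 1 in the first, Tibetan hypoxia replicate 1 in the second and Shouguang hypoxia replicate 2 in the third.

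Tibetan and Shouguang hearts were compared with the conditions averaged, for differences between a highland and a lowland breed. Tibetan hearts had more TRIM47, a ubiquitin ligase gene (2.78 ± 0.13, n = 4 arrays per breed, adjusted p = 1.1e-06), and more HMOX2, the constitutive haem oxygenase (2.08 ± 0.16, adjusted p = 0.000116). They had less NUF2 (-2.07 ± 0.14, adjusted p = 3.89e-05), PLB1, a phospholipase gene (-6.35 ± 0.65, adjusted p = 0.00112), and SLN (-1.72 ± 0.34, adjusted p = 0.0477), which encodes sarcolipin, an inhibitor of the calcium pump. TCF25 (4.11 ± 0.37, adjusted p = 0.000381), RCSD1 (2.86 ± 0.53), PPP6R3 (2.40 ± 0.44), DDTL (2.24 ± 0.33), KLHL7 (2.15 ± 0.37) and NIM1K (1.61 ± 0.26) were also higher. SLC4A1AP (-4.59 ± 0.37, adjusted p = 0.000127), ANK3 (-3.72 ± 0.65), C4 (-1.75 ± 0.32), EPB41L5 (-1.65 ± 0.27) and CDC14A (-1.22 ± 0.24) were lower. In all 127 probe sets passed, 70 higher and 57 lower, of which 96 belong to 90 named genes. Other probe sets of PLB1 moved with it (-3.68) and the other one of NUF2 less (-0.84). Another probe set stood at 0.11 for TRIM47 and at -0.07 for HMOX2. Those of TCF25, SLC4A1AP, RCSD1, PPP6R3, DDTL, KLHL7 and ANK3 barely moved. PLB1, SLC4A1AP and ANK3 lay under the dim limit on all 4 Tibetan arrays and TCF25 on all 4 Shouguang arrays, so the sizes of their changes are bounds only. With signals under the limit raised to it they were -3.50, -2.17, -1.57 and 2.25.

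By group, fatty acid oxidation genes were higher in Tibetan than in Shouguang hearts (median 0.08, 18 of 27, adjusted p = 0.0352; adjusted p = 0.775 with an estimated correlation). Adjusted over the list alone 5 were higher, such as HADHB (0.28 ± 0.07) and ACSL1 (0.51 ± 0.13). The fatty acid transporter CD36 (0.48 ± 0.09) passed over all probe sets. HIF targets were higher (0.11, 23 of 33, adjusted p = 0.0135; adjusted p = 0.197 with an estimated correlation). The collagen-modifying PLOD1 (0.48 ± 0.09, adjusted p = 0.0477) passed over all probe sets and AK3 (0.50 ± 0.14) over the list alone. Smooth muscle genes were lower (-0.33, 8 of 10, adjusted p = 0.00649; adjusted p = 0.197 with an estimated correlation). RGS5 (-0.41 ± 0.10), MYL9 (-0.28 ± 0.07), ABCC9 (-0.65 ± 0.18) and TAGLN (-0.47 ± 0.15) passed, adjusted over the list alone. Cholesterol synthesis was lower (-0.24, 14 of 17, adjusted p = 0.0183; adjusted p = 0.683 with an estimated correlation), with MSMO1 (-0.42 ± 0.13) and ACAT2 (-0.37 ± 0.11) passing, adjusted over the list alone. Heat shock proteins were lower as well (-0.07, 27 of 36, adjusted p = 0.0309; adjusted p = 0.845 with an estimated correlation). HSPB9 (-0.42 ± 0.07) and HSPA8 (-0.45 ± 0.08) passed over all probe sets and CCT6A (-0.35 ± 0.08) over the list alone. The smooth muscle call held without any array in turn, and that of the HIF targets ended without Tibetan normoxia replicate 1 (adjusted p = 0.0893). Cholesterol synthesis lost its call without Shouguang hypoxia or normoxia replicate 1 (up to 0.0956). So did heat shock proteins without Shouguang hypoxia replicate 1, Shouguang normoxia replicate 2, Tibetan hypoxia replicate 2 or Tibetan normoxia replicate 1 (up to 0.167), and fatty acid oxidation without either Tibetan normoxia array or replicate 1 of any other Tibetan or Shouguang group (up to 0.261). A stricter filter and the W-linked covariate each ended these last 3 calls, and median centring that of fatty acid oxidation.

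In lists that did not pass as groups for Tibetan minus Shouguang, NOTCH1, an endothelial signalling receptor (0.68 ± 0.10, adjusted p = 0.0194), the sarcomere gene MYOM1 (0.58 ± 0.10), LAMA2 (0.51 ± 0.08), PDGFRB (0.46 ± 0.09) and the antioxidant gene GPX1 (0.44 ± 0.09) were higher in Tibetan hearts. SOD3, an extracellular superoxide dismutase (-1.12 ± 0.19, adjusted p = 0.0271), TGFB3 (-1.09 ± 0.21), FBLN1 (-0.51 ± 0.09), DLD (-0.49 ± 0.09), RPS14 (-1.03 ± 0.19) and RPL21 (-0.74 ± 0.14) were lower. DLD and RPS14 have 4 tested probe sets each and RPL21 has 5, and only the one with the smallest p is given here. TRIM47 and NUF2 passed under all 12 alternatives for genes and without any array in turn. So did HMOX2 under 11 and TCF25, PLB1 and SLC4A1AP under 10; the others left their probe sets out. The count fell to 25 without Tibetan hypoxia replicate 1, 28 without Tibetan normoxia replicate 2, 29 without Shouguang hypoxia replicate 1, and 44 without Tibetan hypoxia replicate 2 or Tibetan normoxia replicate 1. It was 58 and 78 without Shouguang normoxia replicate 1 and replicate 2, 82 without Dwarf Recessive White hypoxia replicate 2, and 238 without Shouguang hypoxia replicate 2. It was 206 with the stricter filter, 52 with no filter, 18 with no intensity trend, 70 with array weights, 80 with only the arrays compared and 25 with the W-linked level as a covariate. The larger count with the replicate number as a block is given in the part on processing. The share of higher probe sets was 55.1%, and 40.4% with median centring.

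Tibetan and Dwarf Recessive White hearts were compared in the same way. GHR, the growth hormone receptor gene on the Z chromosome, whose defects cause sex-linked dwarfism in chickens, was lower in Tibetan hearts (-1.85 ± 0.14, n = 4 arrays per breed, adjusted p = 5.03e-05). TH, which encodes the rate-limiting enzyme of catecholamine synthesis, was lower (-2.30 ± 0.28, adjusted p = 0.0028), as was ALDH1A1, a retinaldehyde dehydrogenase gene (-2.21 ± 0.33, adjusted p = 0.0097). TRIM47 (2.65 ± 0.13, adjusted p = 1.87e-06) and HMOX2 (2.49 ± 0.16, adjusted p = 1.11e-05) were higher, and NUF2 (-2.04 ± 0.14, adjusted p = 1.57e-05), PLB1 (-4.84 ± 0.65) and SLC4A1AP (-3.43 ± 0.37) lower, again. LOC107052719 (4.84 ± 0.44), SLC4A7, a bicarbonate transporter gene (4.13 ± 0.67), LOC770705 (3.37 ± 0.20), MAP3K2 (2.89 ± 0.36), PPP6R3 (2.25 ± 0.44) and PLG, plasminogen (2.07 ± 0.42), were also higher. UBAC1 (-1.71 ± 0.28) and ADAMTSL1 (-1.61 ± 0.24) were lower. In all 175 probe sets passed, 103 higher and 72 lower, of which 131 belong to 122 named genes. Of the 175, 10 were on Z, 0 on W and 48 not placed. Another probe set of HMOX2 stood at 0.38, one of TRIM47 at -0.07 and one of PLB1 at -2.42, while those of SLC4A7, MAP3K2, PPP6R3 and UBAC1 barely moved. PLB1 and SLC4A1AP lay under the dim limit on all 4 Tibetan arrays, and SLC4A7 and MAP3K2 on all 4 Dwarf Recessive White arrays. Their changes against the limit were -2.15, -1.01, 1.58 and 1.92, which are bounds.

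Plasma protein genes were higher as a group in Tibetan than in Dwarf Recessive White hearts, with 11 of 11 above 0 (median 0.58, adjusted p = 0.000771; adjusted p = 0.323 with an estimated correlation). TTR (1.33 ± 0.30), ALB (2.14 ± 0.50), AHSG (2.85 ± 0.82) and FGG (1.60 ± 0.49) passed, adjusted over the list alone. Cell cycle genes were lower (-0.14, 51 of 62, adjusted p = 8.03e-07; adjusted p = 0.35 with an estimated correlation). NUF2 passed over all probe sets, and SMC4 (-0.38 ± 0.09), CCNA2 (-0.43 ± 0.10) and MCM2 (-0.34 ± 0.09) over the list alone. Oxidative phosphorylation (0.07, 42 of 58, adjusted p = 0.000771; adjusted p = 0.437 with an estimated correlation) and fatty acid oxidation (0.11, 21 of 27, adjusted p = 0.0303; adjusted p = 0.437 with an estimated correlation) were higher. Cardiomyocyte genes were higher too (0.09, 33 of 45, adjusted p = 0.000945; adjusted p = 0.35 with an estimated correlation). NDUFS3 (0.72 ± 0.11, adjusted p = 0.0132) passed over all probe sets, as did AK3 (0.87 ± 0.14, adjusted p = 0.0132) of the HIF targets. HADHB (0.30 ± 0.07) passed over the list alone. The oxidative phosphorylation and cardiomyocyte calls ended with quantile normalization and with median centring. Immediate early genes (0.07, 12 of 16, adjusted p = 0.029; adjusted p = 0.323 with an estimated correlation) and ribosomal protein genes (0.03, 44 of 64, adjusted p = 0.0319; adjusted p = 0.584 with an estimated correlation) were higher. RPL31 (0.69 ± 0.13) passed over all probe sets, and the ribosomal list passed in the opposite direction with quantile normalization (median -0.037, adjusted p = 0.0222). Smooth muscle (-0.15, 8 of 10, adjusted p = 0.0319; adjusted p = 0.323 with an estimated correlation) and neural genes (-0.21, 7 of 9, adjusted p = 0.0378; adjusted p = 0.437 with an estimated correlation), TH among them, were lower. The calls of plasma proteins, the cell cycle, oxidative phosphorylation and cardiomyocytes held without any array in turn. Without Tibetan hypoxia replicate 1 the other 5 calls ended (adjusted p up to 0.306 over the fits that left out an array). The ribosomal call ended also without Tibetan normoxia replicate 1 or replicate 2 of either Dwarf Recessive White group, and the smooth muscle call without Tibetan normoxia replicate 1, Dwarf Recessive White hypoxia replicate 1 or normoxia replicate 2 (up to 0.057). The neural call ended without Tibetan normoxia replicate 2, either Dwarf Recessive White hypoxia array or normoxia replicate 2 (up to 0.145), and with no filter, a stricter filter or median centring. Fatty acid oxidation lost its call without Tibetan normoxia replicate 2 or Dwarf Recessive White normoxia replicate 1 (up to 0.057), and immediate early genes without the latter (up to 0.142). Median centring and the W-linked covariate each ended the fatty acid, immediate early and ribosomal calls, with a ribosomal median of -0.027 under the centring. Quantile normalization ended the fatty acid call, no filter the ribosomal and smooth muscle calls, and median centring the smooth muscle call too.

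Further list members passed singly for Tibetan minus Dwarf Recessive White. The embryonic globin gene HBE (-1.52 ± 0.23, adjusted p = 0.00978) and the class II invariant chain gene CD74 (-0.54 ± 0.09) were lower. So were FBLN1 (-0.74 ± 0.11), GPI (-0.40 ± 0.08), PDIA4 (-0.55 ± 0.11), NFE2L2 (-0.53 ± 0.10), RPS14 (-1.20 ± 0.19) and NDUFS1 (-1.58 ± 0.27; its brightest probe set -0.12). COL4A2, a basement membrane collagen (0.58 ± 0.07, adjusted p = 0.00258), NOTCH1 (0.53 ± 0.10), LAMA2 (0.47 ± 0.08) and DUT (1.39 ± 0.26) were higher. For COL4A2 (6 tested probe sets), RPS14 (4), and CD74, GPI, LAMA2 and DUT (3 each), only the one with the smallest p is given. NUF2, TRIM47 and LOC107052719 passed under all 12 alternatives for genes and without any array in turn, and GHR, HMOX2 and LOC770705 under the 11 that tested their probe sets. The count was 28 with no intensity trend, 91 with 1 probe set per gene and 15 with the W-linked level as a covariate. With the replicate number as a block it was larger, as given in the part on processing. The count also moved in fits that left out an array. It was 72, 96, 81 and 94 without Tibetan hypoxia replicate 1 and 2 and Tibetan normoxia replicate 1 and 2, 83 without Dwarf Recessive White hypoxia replicate 2 and 84 without Dwarf Recessive White normoxia replicate 1.

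**Figure D4:**
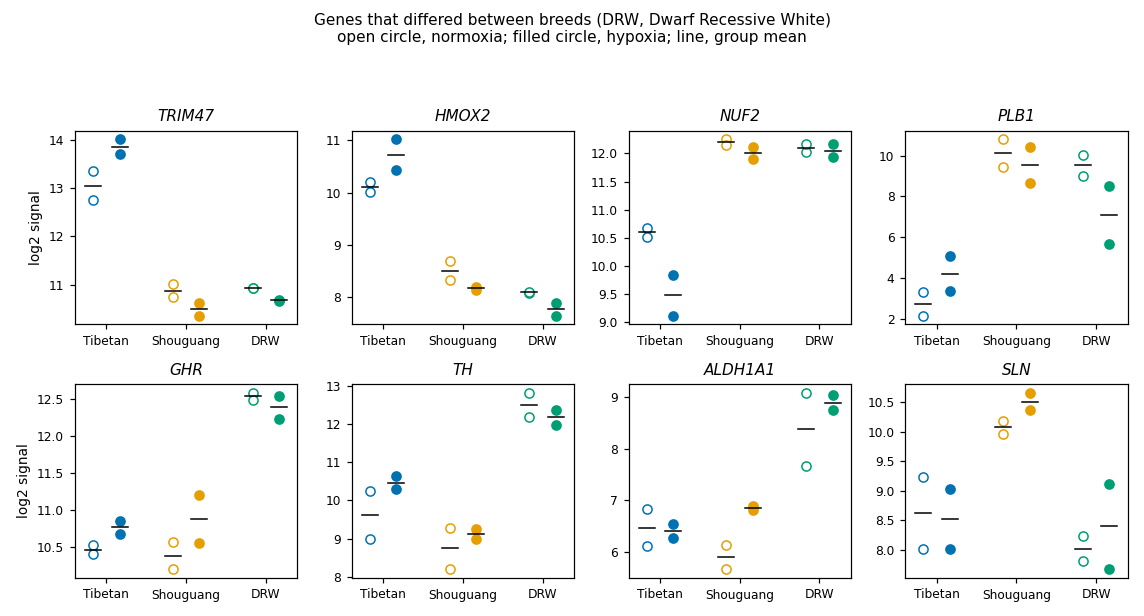
Log2 signal of 8 genes on the 12 arrays, by breed, with open circles for normoxia, filled circles for hypoxia and a line at the mean of each group of 2 arrays. GHR lies at 12.24 to 12.59 on the Dwarf Recessive White arrays and at 10.20 to 11.20 on the others; TRIM47 lies at 12.76 to 14.01 on the Tibetan arrays and at 10.36 to 11.01 on the others.

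Shouguang and Dwarf Recessive White hearts differed in more probe sets than the other pairs of breeds at the adjusted threshold, with 306 passing (154 higher, 152 lower). Of these, 228 belong to 210 named genes. At an unadjusted limma p under 0.05 this pair had the fewest, 2702. Tibetan minus Shouguang had 2820 and Tibetan minus Dwarf Recessive White 2827. TH was lower in Shouguang hearts (-3.41 ± 0.28, n = 4 arrays per breed, adjusted p = 0.000156), as was ALDH1A1 (-2.27 ± 0.33, adjusted p = 0.00559). The chemokine CXCL14 (-3.19 ± 0.65) and the protein kinase gene NIM1K (-2.95 ± 0.26, adjusted p = 0.000197) were lower too. SLN was higher (2.09 ± 0.34, adjusted p = 0.00878). SLC4A7 (4.36 ± 0.67), LOC107052719 (3.96 ± 0.44), LOC770705 (3.03 ± 0.20, adjusted p = 2.83e-05), the chemokine XCL1 (2.999 ± 0.62), MAP3K2 (2.91 ± 0.36), EXOSC1 (2.15 ± 0.29) and SLU7 (1.74 ± 0.18) were also higher. YTHDC1 (-3.04 ± 0.42), THNSL1 (-3.004 ± 0.64), TCF25 (-2.39 ± 0.37) and NDUFS1 (-2.11 ± 0.27; its brightest probe set -0.27) were lower. Other probe sets of SLC4A7, MAP3K2, YTHDC1 and TCF25 barely moved. SLC4A7 and MAP3K2 lay under the dim limit on all 4 Dwarf Recessive White arrays and TCF25 on all 4 Shouguang arrays. Against the limit their changes were 1.81, 1.94 and -0.69. On 3 of 4 arrays of the lower breed this held for XCL1 (1.56 against the limit), EXOSC1 (1.98) and THNSL1 (-2.33). GHR, named here after its values were seen, stood at -1.84 and passed as well.

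Several single list members differed between Shouguang and Dwarf Recessive White hearts. Lower in Shouguang hearts were CD74 (-0.69 ± 0.09, adjusted p = 0.0023), BLB1 (-1.05 ± 0.16, adjusted p = 0.00766), COL14A1 (-0.68 ± 0.10), THBS2 (-0.68 ± 0.11), LAMB1 (-0.48 ± 0.10) and CXCL12 (-0.33 ± 0.07). COL4A2 was higher (0.52 ± 0.07, adjusted p = 0.00348). ARNT, the partner of the HIF alpha subunits, was lower (-0.88 ± 0.14, adjusted p = 0.00766; another probe set -0.42), as were CPT2 (-0.39 ± 0.08), CDCA3 (-0.58 ± 0.12) and DNAJC3 (-1.28 ± 0.27). FADD, an adaptor of death receptors (1.54 ± 0.24, adjusted p = 0.00773), DUT (1.66 ± 0.26), CAT, catalase (0.64 ± 0.12), ALAS1 (0.46 ± 0.09), NEBL (0.42 ± 0.07) and HSPB9 (0.33 ± 0.07) were higher. Only the probe set with the smallest p is given for COL4A2 (6 tested), NEBL (5), and BLB1, COL14A1 and CXCL12 (4 each). The same holds for CD74, CDCA3, DUT and CAT (3 each). As groups, oxidative phosphorylation (median 0.09, 49 of 58, adjusted p = 7.97e-05; adjusted p = 0.476 with an estimated correlation) and cardiomyocyte genes (0.10, 36 of 45, adjusted p = 0.000208; adjusted p = 0.355 with an estimated correlation) were higher. Plasma protein genes were higher as well (0.96, 10 of 11, adjusted p = 0.0037; adjusted p = 0.355 with an estimated correlation). The oxidative phosphorylation and cardiomyocyte calls ended with quantile normalization. The members NDUFB5 (0.26 ± 0.07), ATP2A2 (0.23 ± 0.05) and TTR (1.08 ± 0.30) were higher, adjusted over the list alone. Cell cycle genes (-0.13, 51 of 62, adjusted p = 5.29e-05; adjusted p = 0.355 with an estimated correlation) were lower. CCNA2 (-0.45 ± 0.10), MCM6 (-0.53 ± 0.14), NCAPG (-0.43 ± 0.12) and CENPF (-0.76 ± 0.20) passed, adjusted over the list alone. Neural genes were lower too (-0.27, 6 of 9, adjusted p = 0.0147; adjusted p = 0.355 with an estimated correlation), but not without Dwarf Recessive White normoxia replicate 2, Shouguang hypoxia replicate 2 or Shouguang normoxia replicate 1 (up to 0.231), with no filter or with a stricter one. The stricter filter ended the plasma protein call as well. The count was 100 with no intensity trend, 176 with 1 probe set per gene and 148 with the W-linked covariate. The replicate number as a block raised it. It was 183, 169, 188 and 195 without Dwarf Recessive White hypoxia replicate 1, normoxia replicate 1 and 2, and Shouguang normoxia replicate 1. TH, ALDH1A1, NIM1K, LOC770705, LOC107052719, MAP3K2, EXOSC1, SLU7, YTHDC1, NDUFS1, CD74, DUT and FADD passed without any array in turn and under the alternatives that tested their probe sets, 10 to 12 each.

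Tibetan hearts were also set against the mean of the other breeds within each condition. TRIM47 was higher in normoxia (2.15 ± 0.16, n = 2 Tibetan and 4 other arrays, adjusted p = 0.000232) and in hypoxia (3.28 ± 0.16, adjusted p = 1.69e-06). HMOX2 was higher too (1.81 ± 0.19, adjusted p = 0.00643, and 2.76 ± 0.19, adjusted p = 4.69e-05). NUF2 was lower (-1.55 ± 0.17, adjusted p = 0.00643, and -2.56 ± 0.17, adjusted p = 3.53e-05). SLC4A1AP (-3.87 ± 0.45 and -4.15 ± 0.45) and the polyprenol reductase gene SRD5A3 (-0.85 ± 0.12 and -0.78 ± 0.12) were lower, and LOC770705 was higher (1.82 ± 0.24 and 1.90 ± 0.24). In normoxia TCF25 (3.06 ± 0.46) and KBTBD8 (1.03 ± 0.16) were higher and PLB1 (-7.09 ± 0.80) was lower. In hypoxia CMTM8 (0.67 ± 0.10) was higher, and NSD1 (-2.07 ± 0.32), TENM2 (-1.35 ± 0.20), C4H4ORF32 (-0.97 ± 0.15), LIPT2 (-0.94 ± 0.14), MPP6 (-0.69 ± 0.10) and HSPB9 (-0.60 ± 0.09) were lower. The Tibetan arrays lay under the dim limit for PLB1 in normoxia (-3.50 against the limit), for NSD1 in hypoxia (-1.63) and for SLC4A1AP in both conditions (-1.68 and -1.49), so these changes are bounds. In the breed pairs above, other probe sets of TRIM47, HMOX2, SLC4A1AP and TCF25 moved far less than the ones given here. NSD1 (5 tested probe sets), KBTBD8 (4), C4H4ORF32 (3) and MPP6 (3) are given by the probe set with the smallest p alone. The counts were 11 probe sets in normoxia (7 higher, 4 lower) and 18 in hypoxia (8 higher, 10 lower). Leaving out an array moved both counts, as given in the part on processing. In normoxia the count was 1 with the W-linked level as a covariate and 3 with no intensity trend. In hypoxia it was 4 with the covariate or with no intensity trend.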

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

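In this part, the comparison of the ALB correlation with random gene groups, the reading of the second liver list and the W-linked covariate were chosen only after the values were seen.

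The hypoxia effect differed between breeds, tested on the difference itself with camera, for 12 combinations of a gene list and a pair of breeds, each given here for that difference. With an estimated correlation between genes none of the 12 passed. For Tibetan minus Shouguang the median differences were 0.20 for glycolysis (25 of 26 genes above 0, adjusted p = 7.11e-06), 0.13 for oxidative phosphorylation (51 of 58, adjusted p = 1.23e-05) and 0.11 for fatty acid oxidation (22 of 27, adjusted p = 0.0399). They were 0.80 for plasma proteins of liver and yolk (8 of 11, adjusted p = 0.0399), -0.12 for red blood cells (14 of 20 below 0, adjusted p = 0.0443) and -0.13 for immediate early genes (13 of 16 below 0, adjusted p = 0.0443). The adjusted p with an estimated correlation was 0.607 for each of the 6. Leaving out Shouguang hypoxia or normoxia replicate 1 ended all of these calls but that of glycolysis (adjusted p up to 0.225 for oxidative phosphorylation, 0.879 for fatty acid oxidation, 0.542 for plasma proteins, 0.610 for red blood cells and 0.225 for immediate early genes). The plasma protein call also ended without Tibetan hypoxia replicate 1 or Tibetan normoxia replicate 2, and that of fatty acid oxidation without Shouguang normoxia replicate 2 or any Tibetan array. Red blood cells, whose median was 0.0049 without Shouguang hypoxia replicate 1, lost it without either Tibetan hypoxia array, Tibetan normoxia replicate 1 or either Dwarf Recessive White normoxia array. The immediate early call stood only without Shouguang normoxia replicate 2 or either Dwarf Recessive White normoxia array. Quantile normalization ended the plasma protein, red blood cell, immediate early and fatty acid calls. The stricter filter ended the plasma protein, red blood cell and immediate early calls. The W-linked covariate ended those of plasma proteins (0.170), red blood cells (0.267) and fatty acid oxidation (0.167). No filter ended the fatty acid and red blood cell calls, median centring the fatty acid call, and leaving out the genes on Z and W the red blood cell call.

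For Tibetan minus Dwarf Recessive White the median differences were 0.14 for glycolysis (20 of 26 above 0, adjusted p = 0.00771), 0.21 for HIF targets (24 of 33, adjusted p = 0.0214), 0.076 for oxidative phosphorylation (49 of 58, adjusted p = 0.00553) and 0.21 for fatty acid oxidation (22 of 27, adjusted p = 0.00771). For immediate early genes the median was -0.36 (12 of 16 below 0, adjusted p = 0.000135). With an estimated correlation the adjusted p was 0.141 for immediate early genes, 0.336 for HIF targets and 0.797 for the others. Without Dwarf Recessive White hypoxia replicate 2, Tibetan hypoxia replicate 1 or Tibetan normoxia replicate 2 the first 4 calls ended (up to 0.459 for glycolysis, 0.276 for HIF targets, 0.331 for oxidative phosphorylation and 0.0680 for fatty acid oxidation). Dwarf Recessive White normoxia replicate 1 was needed by the first 3, Dwarf Recessive White normoxia replicate 2 by fatty acid oxidation and Tibetan hypoxia replicate 2 by HIF targets. The HIF target call also ended with no filter, the stricter filter, the W-linked covariate (0.0532) and without the genes on Z and W, and that of oxidative phosphorylation with median centring and the covariate (0.0570). For Shouguang minus Dwarf Recessive White the median of the plasma protein genes was -1.30 (10 of 11 below 0, adjusted p = 0.00272; adjusted p = 0.983 with an estimated correlation). That call ended without Shouguang hypoxia or normoxia replicate 1 (up to 0.103) and with the W-linked level as a covariate (0.287). The calls of glycolysis for Tibetan minus Shouguang and of immediate early genes for Tibetan minus Dwarf Recessive White held without any array in turn and under 8 of 8 alternatives for lists at the preset correlation.

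The plasma protein genes fell in hypoxia on average over the breeds, with a median of -1.37 over 11 genes (adjusted p = 2.29e-06; adjusted p = 0.178 with an estimated correlation), ALB (-2.83), TTR (-1.62) and AHSG (-4.05, or -1.91 against the dim limit) among them, while APOA1 (0.71) rose. A second list of 53 liver genes, of which 21 were measured, had a median of 0.04, at percentile 73.0 among 10000 random lists matched on level. The bound set beforehand counted that value against less liver tissue on the hypoxia arrays; it was the wrong bound, since members went both ways (11 above and 10 below 0; FBP1 at -0.87, PLG at -0.80 and GC at -0.63 against LECT2 at 0.75), so that less liver tissue and a lower transcription of these genes cannot be told apart. Once the group means were taken out, ALB varied with 6 other falling genes with a median r of 0.658 (0.509 to 0.913). This lay at percentile 99.97 among random gene groups, whose median was 0.0550. With 2 arrays per group the deviations mirror each other, so each r over the 12 arrays rests on 6 differences. A carried-over tissue that differs between arrays would give such values. Genes regulated together would too, since the random groups were matched on level only, so the test cannot decide. Other genes also vary along the replicate numbers, but the plasma protein list did not pass by number in camera (median of replicate 2 minus 1 -0.090, adjusted p = 0.550). Hypoxia itself, which the design names, stays open and was not tested apart from these explanations.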

How the results depend on the processing

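In this part, the W-linked level as a covariate and leaving out the genes on Z and W were chosen only after the result was seen, and every other alternative was fixed before. Of 6741 values under an alternative, 5422 kept their call or count, which for 4103 gene values and 1098 list values means the same side of the threshold and for 221 counts a change within 1.5 times. Among these genes 64 values changed sign, all of genes that passed neither in the report's fit nor in the alternative. Of the rest, 1181 no longer passed (916 of genes, 265 of gene lists), 25 newly passed, 111 counts moved by more than 1.5 times and 2 reversed.

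With the replicate block, the number of an array as a further factor, the counts were 3 probe sets for hypoxia in Dwarf Recessive White, 81 for the mean hypoxia effect, 605 for Tibetan minus Shouguang, 579 for Tibetan minus Dwarf Recessive White and 711 for Shouguang minus Dwarf Recessive White, against 1, 13, 127, 175 and 306 without it. It gave 40 and 89 for Tibetan against the others in normoxia and hypoxia, against 11 and 18. All 13, 127, 175 and 306 remained among those called. The block ended the neural list call of Tibetan minus Dwarf Recessive White (adjusted p = 0.0581) and, for the hypoxia effect of Tibetan minus Shouguang, those of plasma proteins (0.0680), red blood cells (0.0624) and immediate early genes (0.0540). The block takes the differences between replicate numbers out of the residual variance. The numbers were not taken as pairs: once group means were removed, same-numbered arrays correlated at 0.0586 to 0.199 over the 15 pairs of groups, 7 of them above 0.1. In these deviations, which mirror each other within a group, that makes each array vary more with its own number than with the other one. The first component within groups, 26.2% of the variance, also parted the numbers in all 6 groups; both are hints from the data and not from the design.

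With the W-linked level as a covariate the same 7 counts were 0, 7, 25, 15, 148, 1 and 4, with 6 of the 13, 25 of the 127, 13 of the 175 and 140 of the 306 probe sets kept; a covariate that differs between breeds takes part of their contrast with it. Without the genes on Z and W every count stayed within 1.5 times. Without the intensity trend the 7 counts were 0, 0, 18, 28, 100, 3 and 4, with 0, 15, 27 and 96 kept; the cause was not tested.

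The filter on dim probe sets, with its effect on the number of tests, changed the mean hypoxia effect to 4 with none and 26 with the stricter one, Tibetan minus Shouguang to 52 and 206, and Tibetan against the others in hypoxia to 6 with none. Median centring gave 20 for the mean hypoxia effect and 2 for hypoxia in Dwarf Recessive White, and the offset gave 24 for the mean hypoxia effect. Array weights gave 70 for Tibetan minus Shouguang. The cause of these changes was not tested. Fits with only the arrays compared, which have fewer arrays to estimate the variance, gave 7 for Dwarf Recessive White, 80 for Tibetan minus Shouguang and 11 for Tibetan against the others in hypoxia. With 1 probe set per gene, which means fewer tests, the counts were 2 for hypoxia in Shouguang (0 before), 3 in Dwarf Recessive White and 32 for the mean hypoxia effect. They were 91 and 176 for Tibetan and Shouguang minus Dwarf Recessive White, and 4 for Tibetan against the others in normoxia.

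At an adjusted p of 0.1 the counts were 3 for Dwarf Recessive White, 48 for the mean hypoxia effect, 391, 397 and 581 for the breed pairs in the order used above, and 28 for Tibetan against the others in hypoxia. With a change of at least 2-fold they were 8 for the mean hypoxia effect and 48, 77 and 109 for the breed pairs.

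Of the 65 list calls 1 stood with an estimated correlation, which allows for genes that vary together. The ribosomal list reversed for Tibetan minus Dwarf Recessive White with quantile normalization (median -0.037, adjusted p = 0.0222); the cause was not tested. It also reversed for hypoxia in Shouguang without Shouguang hypoxia replicate 2 (median -0.0023, adjusted p = 0.865), from 1 array in that group; its median ran from -0.0056 to 0.073 over the fits without an array, and below 0 it also lay without Shouguang normoxia replicate 2, where the test pointed up. In 2 more list calls that ended the median alone changed sign: ribosomal genes of Tibetan minus Dwarf Recessive White with median centring (-0.027), and red blood cells for the hypoxia effect of Tibetan minus Shouguang without Shouguang hypoxia replicate 1 (0.0049). Scaling moved the median of all tested probe sets by less than 0.1.

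Leaving out each array in turn, where a lone array is assumed to vary like the other groups, gave 0 to 9 probe sets for hypoxia in Tibetan, 0 to 3 in Shouguang, 0 to 23 in Dwarf Recessive White and 2 to 17 for the mean. For the differences of effects it gave 0 to 2, 0 to 7 and 0 to 15, and for the breed pairs 25 to 238, 72 to 204 and 169 to 275. Tibetan against the others had 5 to 18 in normoxia and 6 to 25 in hypoxia, and the lists 48 to 78 calls. With 2 arrays per group the standard error limits what a within-breed effect can show. Signal over background limits dim genes: the 40% of probe sets with the lowest mean signal were not tested, and no change can be read for them.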

Other observations

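In this part, the tests of the W-linked genes, the ratio between probe sets and the comparison of replicate numbers were chosen only after the result was seen.

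The breeds' hypoxia effects were compared across 10276 genes, which are not independent replicates. Pearson's r was 0.198 between Tibetan and Shouguang, 0.106 between Tibetan and Dwarf Recessive White and 0.0629 between Shouguang and Dwarf Recessive White. At an unadjusted p under 0.05 in both breeds of a pair stood 82, 67 and 111 genes, 76, 56 and 95 of them with the same sign. The numbers expected from independent effects, 29.96, 29.2 and 38.9, are no chance level, since breeds shared a gene's variance. Among the genes of the mean hypoxia effect, MGP (-0.99), BLB1 (-1.05), ACCSL (-1.09) and FKBP1B (-0.65) also passed as lower in Shouguang, and MGP (-0.64) in Tibetan, than in Dwarf Recessive White hearts.

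Arrays numbered replicate 1 and replicate 2 differed across the 6 groups. With group and number in the model, 1260 probe sets passed, 617 higher and 643 lower in replicate 2. Their median absolute log2 change was 0.40, and 19 changes were at least 2-fold. Those with a name belong to 902 genes. MSN, LRRC8C, U2AF1, CDO1, TTN and PECAM1 were higher in replicate 2, and ATP2B4, TIMP3, EFNB1, COL5A1, SLC4A1 and GATA5 lower. No gene list passed by camera (smallest adjusted p = 0.126). What the numbers stand for is not given in the sources used here.

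The W-linked genes differed between arrays, with a mean log2 signal from 6.01 to 9.60. Against the general quality of an array, autosomal genes of matched level on Dwarf Recessive White normoxia replicate 1 had a median deviation from the other arrays of -0.0097, while the W-linked genes had one of -2.85. Against a common effect of hypoxia, the W-linked mean changed by 0.16 in Tibetan, -1.02 in Shouguang and 1.61 in Dwarf Recessive White hearts, a spread of 2.63, and the normoxia arrays of Dwarf Recessive White alone were 2.41 apart. A candidate explanation is the share of female embryos behind an array, since the Z-linked mean ran against the W-linked one with a Pearson r of -0.782. The sex of the embryos is not given in the sources used here, and an effect of hypoxia in a single breed was not tested apart from it.

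Breed differences were often read by 1 probe set of a gene. In 282 pairs of a called gene and a contrast, over 213 genes with a further probe set, the median ratio of the other probe set's change to the called one's was 0.207 (95% bootstrap interval 0.127 to 0.265), 0.0747 for 105 called changes of at least 2-fold and 0.305 for the other 177. The ratio is in line with sequence variants of a breed, or transcript forms, under single probe sets, although choosing the called probe set by its p lowers it too. Of the other probe sets 95 (33.7%) changed the same way at an unadjusted p under 0.05 and 68 had the opposite sign; the share lay between the bounds set beforehand, so that for these genes breed differences in the whole transcript level cannot be told apart from the first explanation. The genotypes of the breeds, which the design sets apart, stay open and were not tested.

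Other splits of the arrays were fitted with simpler models than the contrasts above, so counts of the real splits can differ from those given there. For a breed pair the split was the only term. For the mean hypoxia effect, with each breed's arrays parted into 2 and 2 and breed in the model, 2 of 100 splits called as many probe sets as the real one, which called 23. The highest other split, with 984, followed the replicate number and points to a structure of the samples; with the number as a block the mean effect had 81. For the breed pairs, 1 of 35 splits of 8 arrays into 4 and 4, the real one, called as many. The real splits called 127 for Tibetan minus Shouguang, 205 for Tibetan minus Dwarf Recessive White and 254 for Shouguang minus Dwarf Recessive White, and the highest others 63, 33 and 6. These others also followed the replicate number and point to the same structure. In all 4 comparisons a share under 0.05 of the splits called as many probe sets as the real one. For a breed pair, 1 of 35 is the lowest share that the splits can give. Since the arrays also differ along the replicate number, they are not interchangeable. This share alone therefore excludes neither chance nor such a structure.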
